A study of Mus musculus with 12 samples.

How the data were processed

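RNA was sequenced from invariant natural killer T (iNKT) cells, T cells with a semi-invariant receptor for lipid antigens, sorted from the thymi of C57Bl/6J mice 4 to 5 weeks old. Per the labels' protocols, cells binding the tetramer and positive for the T cell receptor beta chain were sorted as stage 0 (CD24 positive, CD44 negative) or stage 1 (CD24 negative, CD44 negative). Thymi of 4 to 7 mice were pooled, wild type (WT) or carrying a Cre transgene with floxed Bcl6 alleles (Bcl6KO). RNA was taken up with a QIAGEN column kit and libraries were made with NuGEN's kit for very low RNA inputs. The 12 libraries form 4 groups of 3, taken from the genotype, stage and replicate number in the sample titles. The labels do not say whether the 3 libraries of a group came from separate pools, so p-values measure the spread between these libraries, part of which may be technical. Chromatin accessibility libraries of the same populations were not analysed here.

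The deposited values are raw counts per gene, 1 file per library, for the same 48672 Ensembl gene IDs in each. Per the submitters' processing notes, bcl2fastq, TopHat2, Bowtie2 and DESeq were used with the mouse build mm10; their versions, the counting program, the annotation and the strand setting are not given in the sources used here. Of the IDs, 48312 matched a symbol of GENCODE release M21 on the same build, which also gave the coordinates. The remaining IDs named a gene by ID and stayed in the tests; their counts made up 0.195% to 0.366% of a library. Reads of overlapping or antisense genes cannot be told apart where counting did not use strand. The share of each named gene's exonic bases covered by another gene was computed, except for Ddx3y and Eif2s3y. Among the genes named in the text it was above 5% for Hectd2 (20.2%), Lef1 (13.7%), Xist (12.6%), Il4ra (9.51%), Ccnd2 (7.86%), Malat1 (7.72%), Myb (6.26%), Bcl2 (6.09%), Lig1 (5.79%), Pfkp (5.58%), Bach2 (5.40%) and Maf (5.34%). Their counts may include reads of another gene, to an extent that the share of bases does not bound.

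Library totals were scaled by the trimmed mean of M-values (TMM). No pair of libraries within a group agreed within sampling noise, with a chi-square per gene between 30.6 and 188, so all 12 were kept as separate samples. A count of 0 allows up to 3 counts in a library (0.569 to 0.615 CPM). Folds against a group with 0 counts in all libraries were computed against the mean of that floor over the group's libraries. These libraries carry no molecular identifiers, so floors cover counting error only. Levels are CPM from edgeR's cpm function, on the TMM-scaled library size, as mean ± SD of 3 libraries.

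Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing edgeR's filterByExpr by group (15704) were fitted with robust quasi-likelihood dispersion over all 12 libraries, with 1 mean per group, which leaves 8 residual degrees of freedom. The contrasts were tested with the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment at 0.05: Bcl6KO against WT at each stage, stage 1 against stage 0 in each genotype, and the difference between the genotype effects of the stages. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.835.

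Before the data were examined, 34 gene lists were written from textbook knowledge of thymocytes, iNKT subsets, cell biology and other cell types a sort could hold, and 31 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the lists within a contrast, and again with the correlation estimated per list and with fry. Named genes followed a rule fixed at the same time. In every comparison it took Bcl6, Zbtb16, Cd24a and Cd44. It added up to 6 genes with the largest rise and 6 with the largest fall among genes past the threshold. These had at least 5 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted models, pseudogenes, receptor segments and mitochondrial and sex-linked genes. Up to 2 risen and 2 fallen members per list followed, by lowest p, or the member with the highest level. Genes outside the rule are marked as chosen after their values were seen.

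The procedure was tested on simulated counts of the 15704 genes, with 50 genes changed at each fold of 2, 4, 8 and 16. It found 0, 3, 21 and 27 of these for Bcl6KO against WT at stage 0, and 0, 1, 19 and 23 at stage 1. The numbers were 0, 6, 14 and 26 for the stages in WT, 0, 11, 21 and 29 for the stages in Bcl6KO, and 0, 0, 3 and 6 for the difference between genotype effects. False calls numbered 1, 0, 2, 1 and 0 in the same order, and DESeq2 1.42.0 on the same data made 70, 41, 87, 63 and 66 false calls. A 4-fold change was thus mostly missed at this spread and number of libraries. Apart from the set folds, each simulated gene had the same mean and edgeR's own dispersion in every group. The real groups differed in spread (replicate r 0.678 to 0.738 in Bcl6KO stage 0, 0.871 to 0.903 in WT stage 1). The simulation thus neither shows that edgeR's errors were controlled in these data nor ranks it fairly against DESeq2. Alternatives fixed beforehand were other size factors, filters, DESeq2, a fold threshold, only the groups compared, a replicate block, nonrobust dispersion and leaving out each library. Others were added after the uneven libraries were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.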

Results

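The series asks how the transcriptional repressor BCL6 acts in early innate-like T cells, and its labels give 2 genotypes at 2 stages. Gene counts were available for 12 libraries, 3 for each of WT stage 0, WT stage 1, Bcl6KO stage 0 and Bcl6KO stage 1. Library totals ran from 4129919 to 8038717 counts. The Bcl6KO stage 0 libraries had the fewest genes detected, 16287 ± 1437, against 19770 ± 1649 in WT stage 0, 21391 ± 564 in WT stage 1 and 20133 ± 983 in Bcl6KO stage 1. In the same libraries Sp100, a nuclear body gene on chromosome 1 (85649988 to 85709998), took 17.5 ± 6.57% of counts, against 3.32 ± 2.86%, 0.333 ± 0.523% and 2.14 ± 1.92%. The Sp100 difference between genotypes did not pass the test at stage 0 (log2 fold change 2.85, SE 1.96, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.544).

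Bcl6 itself (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852, minus strand) was counted at 288 ± 78.9 CPM in WT stage 0 and 607 ± 83.0 CPM in libraries labelled Bcl6KO stage 0. At stage 1 it stood at 7.18 ± 2.63 CPM in WT and 32.0 ± 21.5 CPM in Bcl6KO (SD, n = 3 each). Neither genotype difference passed the edgeR quasi-likelihood test (log2 fold change 1.07, SE 0.44, Benjamini-Hochberg adjusted p = 0.285 at stage 0, and 2.15, SE 0.47, adjusted p = 0.624 at stage 1). The count covers the whole gene and the deleted exons are not given in the sources used here, so it checks neither the deletion nor the genotype labels. Cd24a, the CD24 surface glycoprotein used in the sort, stood at 167 ± 15.7 and 242 ± 81.1 CPM in WT and Bcl6KO stage 0. At stage 1 it stood at 5.84 ± 6.93 and 1.33 ± 0.498 CPM. Cd44, the hyaluronan receptor that both gates excluded, was low throughout, between 1.09 ± 0.792 CPM in Bcl6KO stage 0 and 16.4 ± 8.52 CPM in Bcl6KO stage 1. Zbtb16, which encodes PLZF, the transcription factor that directs the innate-like program, stood at 166 ± 60.9 and 50.5 ± 43.0 CPM at stage 0 in WT and Bcl6KO. Its stage 1 levels were 544 ± 120 and 356 ± 73.9 CPM. The genotype difference of Zbtb16 did not pass at stage 0 (log2 fold change -1.72, edgeR adjusted p = 0.226) or at stage 1 (-0.61). Nor did those of Cd24a and Cd44 at either stage.

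**Figure D1:**
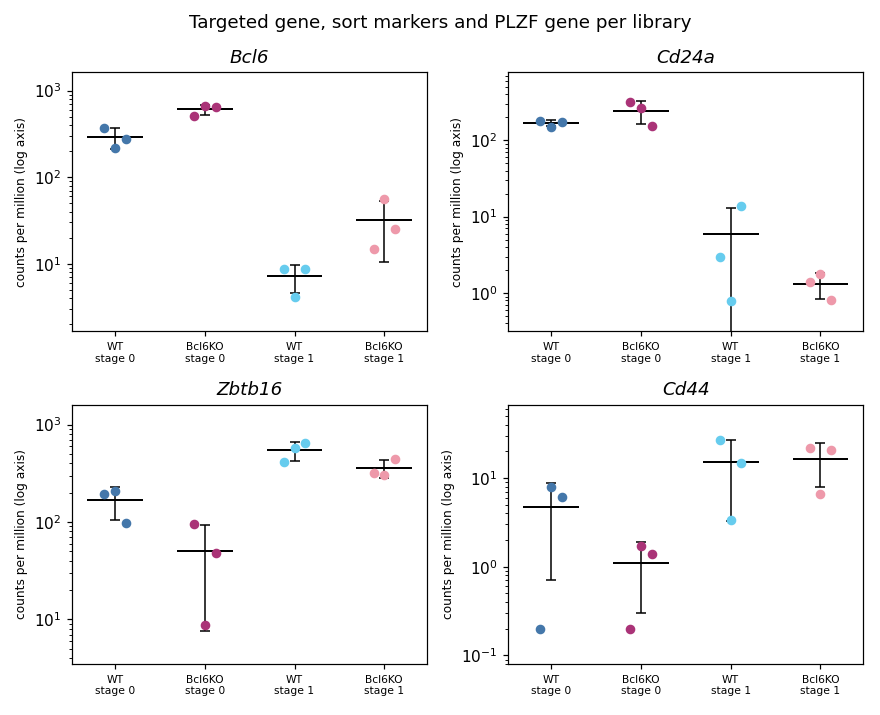
CPM (log axis) of Bcl6, Cd24a, Zbtb16 and Cd44 in each of the 12 libraries, with the mean as a long line and the SD as a bar that stops at 0.1 CPM. Bcl6 averaged 288 CPM in WT and 607 CPM in Bcl6KO at stage 0, and Cd24a fell below 6 CPM on average at stage 1 in both genotypes.

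In WT cells, passage from stage 0 to stage 1 came with lower levels of double-positive thymocyte genes. Arpp21, a phosphoprotein gene abundant in immature thymocytes, fell from 250 ± 145 to 0.400 ± 0.344 CPM (SD, n = 3 each). Cd8a, the CD8 coreceptor, fell from 216 ± 132 to 0.726 ± 0.694 CPM, and Rag1, the recombinase that assembles antigen receptor genes, from 226 ± 234 to 3.11 ± 2.52 CPM. Bcl6 fell from 288 ± 78.9 to 7.18 ± 2.63 CPM and Itm2a, a membrane protein gene switched on at positive selection, from 452 ± 93.0 to 7.88 ± 1.99 CPM. Icos, an inducible costimulatory receptor, rose from 264 ± 136 to 1684 ± 127 CPM. Il7r, the interleukin 7 receptor alpha chain, rose from 59.5 ± 52.5 to 519 ± 37.5 CPM, and Arl4c, a small GTPase, from 46.3 ± 21.8 to 370 ± 70.6 CPM. In all, 11 genes rose and 57 fell of 15704 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1319 had an unadjusted p under 0.05, against 785 expected by chance.

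Largest among the rises were Csf1, a growth factor of macrophages (log2 fold change 7.92, SE 1.49), F2rl1, a receptor activated by proteases (5.99, SE 1.14), and Paqr8, a membrane progestin receptor (5.62, SE 1.06). Their edgeR adjusted p was 0.0392, 0.0393 and 0.0393. Each was at or below 0.461 CPM on average in stage 0, under the floor of 0.592 CPM, so the sizes of these rises are uncertain. So is the size of the fall of Arpp21, at 0.400 CPM in stage 1 against a floor of 0.602 CPM. The steepest falls were those of Arpp21 (-9.20, SE 1.00, edgeR adjusted p = 9.94e-04), Cd8a (-8.16, SE 0.98, adjusted p = 0.00214) and Rag1 (-6.17, SE 1.04, adjusted p = 0.0200). Tnfsf8, the CD30 ligand (-6.02, SE 0.84, edgeR adjusted p = 0.00556), followed, with Itm2a (-5.84, SE 0.51, adjusted p = 3.94e-04) and Bcl6 (-5.32, SE 0.53, adjusted p = 9.61e-04). Cd24a also fell (-4.83, SE 0.78, edgeR adjusted p = 0.0155), whereas Zbtb16 (1.71, SE 0.59, adjusted p = 0.387) and Cd44 (1.66, SE 1.22, adjusted p = 0.812) did not pass.

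Double-positive thymocyte genes fell as a list (median log2 fold change -1.67, 25 tested, 4 fallen, 11 fallen adjusted over the list alone, camera adjusted p = 1.01e-19, adjusted p = 0.00806 with an estimated correlation). TCR-induced and post-selection genes also fell (median -1.02, 7 of 29 fallen and 1 risen, 13 and 4 adjusted over the list alone, camera adjusted p = 3.71e-10, adjusted p = 0.0153 with an estimated correlation). Among them Egr2, an early growth response factor needed for iNKT cells, fell from 484 ± 121 to 75.1 ± 26.1 CPM (-2.69, SE 0.35, edgeR adjusted p = 0.00343). Icos, on the same list, rose (2.67, SE 0.34, edgeR adjusted p = 0.00310). Early iNKT transcription regulators fell (median -0.46, 6 of 24 fallen, 8 fallen and 3 risen adjusted over the list alone, camera adjusted p = 2.36e-07, adjusted p = 0.0438 with an estimated correlation). Myb, a progenitor regulator, stood at -2.69 (SE 0.28, edgeR adjusted p = 9.94e-04) and Bach2, a repressor of effector programs, at -2.90 (SE 0.32, adjusted p = 0.00103). Without WT stage 0 library 1 the list's median was -0.13. Tfh-associated genes, those of follicular helper T cells, fell (median -0.95, 5 of 21 fallen and 1 risen, 8 and 2 adjusted over the list alone, camera adjusted p = 1.01e-05, adjusted p = 0.0378 with an estimated correlation). Lef1, a Wnt-pathway factor, fell on that list (-2.75, SE 0.38, edgeR adjusted p = 0.00484), as did Tnfsf8. Interferon-stimulated genes rose as a list (median 1.27, 28 of 30 positive, 0 past the edgeR test over all genes or adjusted over the list alone, camera adjusted p = 3.71e-10, adjusted p = 0.0153 with an estimated correlation). Parp14, their most abundant member, stood at 147 ± 5.38 CPM in stage 0 and 276 ± 65.0 CPM in stage 1.

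Several effector and housekeeping lists differed at WT stage 1 by camera under the preset correlation and not with an estimated one. Fry, a test that allows for correlated genes, called all of these but the cytosolic ribosomal protein genes (fry adjusted p = 0.0823) and the iNKT receptor segments (0.107). MHC class I genes had a median of 0.97 (1 of 16 risen, 5 adjusted over the list alone, camera adjusted p = 3.99e-06, adjusted p = 0.0875 with an estimated correlation). B2m, the light chain of class I molecules, rose from 607 ± 311 to 2536 ± 333 CPM (2.06, SE 0.33, edgeR adjusted p = 0.0155). Medians of 1.44 for NKT1, 1.68 for NKT2 and 2.03 for NKT17 effector genes gave camera adjusted p = 1.40e-04, 2.24e-04 and 0.00445, or adjusted p = 0.116, 0.0755 and 0.0875 with an estimated correlation. No NKT1 or NKT17 gene passed the edgeR test. Mature single-positive and egress genes (median 1.59, Il7r risen, Cd2 and Dgka fallen) gave camera adjusted p = 1.40e-04, and adjusted p = 0.0875 with an estimated correlation. Cell cycle genes (median 0.85, 38 of 40 positive, 1 risen adjusted over the list alone) gave camera adjusted p = 6.09e-08, and adjusted p = 0.139 with an estimated correlation. Cytosolic ribosomal protein genes (median 0.46, 57 of 58 positive, 0 adjusted over the list alone) gave camera adjusted p = 8.07e-06, and adjusted p = 0.330 with an estimated correlation. Other shares of the RNA moved along, Malat1 from 2.66 ± 0.27% to 1.05 ± 0.41% of counts and rRNA-like genes from 2.83 ± 0.51% to 5.34 ± 1.38%. Cell adhesion genes (median 0.92, adjusted p = 0.00333), BCL6-repressed genes (1.17, 0.0146), SLAM family genes (-0.50, 0.00247) and iNKT receptor segments (-0.69, 0.00459) passed camera. In that order they had adjusted p = 0.0875, 0.116, 0.0798 and 0.285 with an estimated correlation. Gamma-delta T cell markers, several of which NKT17 cells also use, had a median of 2.76 (camera adjusted p = 1.43e-09, adjusted p = 0.0875 with an estimated correlation). Without WT stage 0 library 2 the gamma-delta median was 7.08 and the NKT1 median 2.28. Without WT stage 0 library 3 the BCL6-repressed median was 0.74 and the ribosomal one 0.30. Single genes of other lists fell as well, including Il21r and Il4ra, cytokine receptors (-3.02 and -4.73, edgeR adjusted p = 0.00630 and 0.0179), and the survival gene Bcl2 (-3.20, adjusted p = 0.0114). The glycolytic genes Pfkp and Ldhb (-1.49 and -2.88, edgeR adjusted p = 0.0179 and 0.0417), the homotypic receptor gene Slamf6 (-1.99, adjusted p = 0.00556) and the activation marker Cd69 (-4.53, adjusted p = 0.0320) fell too.

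The WT stage count rested on single libraries. It was 20, 24 or 30 without WT stage 1 library 1, 2 or 3, and 25, 139 (59 risen, 80 fallen) or 26 without WT stage 0 library 1, 2 or 3. It was 105 without Bcl6KO stage 0 library 2 and 45 without Bcl6KO stage 1 library 2. Arpp21, Cd8a, Itm2a, Bcl6, Egr2, Myb, Bach2, Cd2, Lef1, Icos and Arl4c kept their calls in all 25 alternatives. Other calls were less steady, and passed in 11 for Paqr8, 12 for Csf1 and Dgka, 13 for Ldhb, 15 for F2rl1 and Cd69 and 16 for Il7r. The other genes named so far as called between WT stages passed in 18 to 24.

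In cells labelled Bcl6KO, the same passage again came with lower levels of double-positive thymocyte genes. Rag1 fell from 199 ± 121 to 0.132 ± 0.115 CPM and Dntt, the terminal transferase of receptor gene assembly, from 41.7 ± 27.7 to 0.133 ± 0.230 CPM (SD, n = 3 each). Cd24a fell from 242 ± 81.1 to 1.33 ± 0.498 CPM and Cd8a from 140 ± 53.3 to 2.52 ± 1.33 CPM. Bcl6 fell from 607 ± 83.0 to 32.0 ± 21.5 CPM. Il17rb, a receptor chain for interleukin 25, rose from 19.6 ± 14.7 to 234 ± 77.5 CPM. Icos rose from 293 ± 75.3 to 1065 ± 55.4 CPM and Cxcr6, a chemokine receptor of iNKT cells, from 1.31 ± 2.27 to 134 ± 62.0 CPM. In all, 66 genes rose and 40 fell of 15704 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 2577 had an unadjusted p under 0.05.

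The log2 fold changes of these falls were -10.31 (SE 1.36, edgeR adjusted p = 0.00658) for Rag1 and -8.05 (SE 1.58, adjusted p = 0.0427) for Dntt. Both genes lay under the floor of 0.597 CPM at stage 1, so the sizes of their folds are uncertain. Fold changes were -7.49 (SE 0.90, edgeR adjusted p = 0.00633) for Cd24a, -5.78 (SE 0.86, adjusted p = 0.0136) for Cd8a and -4.25 (SE 0.49, adjusted p = 0.00633) for Bcl6. Of the 106 genes, 14 had 0 counts in all libraries of 1 group, 13 of them in Bcl6KO stage 0. Against the floor of 3 counts per library, Ckap4, a membrane protein of the endoplasmic reticulum, was at least 26.7-fold, Alg14, of protein glycosylation, 26.0-fold and Hbegf, a growth factor, 25.7-fold higher at stage 1. Cptp, a lipid transfer protein, was at least 23.7-fold, Zbtb45, a zinc finger gene, 23.2-fold and Slc4a8, a bicarbonate transporter, 21.95-fold higher. Dmwd, a WD repeat gene, was at least 54.6-fold lower. The zeros of the first 6 lay in the Bcl6KO stage 0 libraries, which had the fewest genes detected and the highest Sp100 share. In WT stage 0 Ckap4 stood at 14.0 ± 10.6 CPM. Of 25 alternatives, Ckap4, Alg14 and Hbegf passed in 6, Slc4a8 in 7, Cptp in 10, and Zbtb45 and Dmwd in 11. Zbtb16 (2.82, SE 0.62, edgeR adjusted p = 0.0571) and Cd44 (3.87, SE 1.35, adjusted p = 0.176) did not pass.

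Double-positive thymocyte genes fell (median -1.18, 5 of 25 fallen, 13 adjusted over the list alone, camera adjusted p = 2.33e-15, adjusted p = 0.0142 with an estimated correlation). Rag1 and the gate marker Cd24a were among them. TCR-induced and post-selection genes fell (median -0.77, 4 of 29 fallen and 1 risen, 9 and 2 adjusted over the list alone, camera adjusted p = 3.14e-07, adjusted p = 0.0296 with an estimated correlation). On that list Itm2a fell, at -3.52 (SE 0.45, edgeR adjusted p = 0.00633) and Nr4a1, an immediate target of receptor signalling, at -4.16 (SE 0.68, adjusted p = 0.0218). The list's median was -0.41 without Bcl6KO stage 0 library 2. Early iNKT transcription regulators fell (median -0.65, 3 of 24 fallen, 11 fallen and 1 risen adjusted over the list alone, camera adjusted p = 1.41e-06, adjusted p = 0.0431 with an estimated correlation). Myb fell, at -2.19 (SE 0.28, edgeR adjusted p = 0.00633) and Hivep3, a zinc finger regulator of iNKT cells, at -2.20 (SE 0.38, adjusted p = 0.0256). Interferon-stimulated genes rose as a list (median 1.59, or 1.46 with zero-count genes at their bound, 27 of 30 positive). None had risen over all genes and 12 had adjusted over the list alone (camera adjusted p = 7.26e-10, adjusted p = 0.0296 with an estimated correlation).

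NKT2 effector genes were higher at Bcl6KO stage 1 under the preset correlation (median 2.82, 4 of 13 risen, 8 risen and 3 fallen adjusted over the list alone, camera adjusted p = 2.89e-04, adjusted p = 0.172 with an estimated correlation). Il17rb (3.58, SE 0.59, edgeR adjusted p = 0.0218) and Icos rose (1.86, SE 0.33, adjusted p = 0.0278). NKT1 effector genes had a median of 2.85 (1.38 with zero-count genes at their bound, 0 risen, 4 adjusted over the list alone, camera adjusted p = 0.00783, adjusted p = 0.377 with an estimated correlation). Their call ended with the Sp100 share as a covariate (camera adjusted p = 0.138), and their median was 1.63 without Bcl6KO stage 1 library 1. MHC class I genes (median 1.13, B2m risen, camera adjusted p = 8.42e-04), mature single-positive and egress genes (1.17, Gimap4 and Ly6a risen, 0.00169) and gamma-delta T cell markers (4.90, or 4.46 at the bound, Maf risen, 6.50e-08) passed. Each had adjusted p = 0.282 with an estimated correlation. B2m rose by 1.91 (edgeR adjusted p = 0.0256), Maf, a transcription factor of NKT17 cells, by 5.51 (0.0496), Gimap4, a GTPase, by 3.85 (0.0221) and Ly6a, which encodes SCA-1, by 7.64 (0.0489). B cell markers (median -1.64, camera adjusted p = 0.0119), ribosome biogenesis genes (-0.43, 0.0451) and Tfh-associated genes (median -0.58 with a mean of 0.00, 0.0491) passed camera as well. They had adjusted p = 0.237, 0.282 and 0.282 with an estimated correlation. The B cell call ended without Bcl6KO stage 0 library 1 (camera adjusted p = 0.136), and its median lay between -3.16 and -2.56 without any 1 of 10 other libraries. The mature single-positive median was 0.73 or 0.75 without Bcl6KO stage 0 library 2 or 3. The ribosome biogenesis call ended without any of 4 Bcl6KO libraries (camera adjusted p up to 0.184) and the Tfh-associated call without any of 6 libraries (up to 0.189). Without Bcl6KO stage 0 library 1 the medians were -0.26 and -0.33, and the Tfh-associated one was -0.35 without Bcl6KO stage 1 library 1. Single genes that fell included the proapoptotic Bcl2l11 (-3.19, edgeR adjusted p = 0.0278), and the CD8 beta chain gene Cd8b1 (-3.51, adjusted p = 0.0489). Il21r (-2.17, edgeR adjusted p = 0.0415) and the immediate-early gene Egr1 (-2.10, adjusted p = 0.0253) fell too.

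The Bcl6KO stage count was 277, 65 or 35 without Bcl6KO stage 0 library 1, 2 or 3, and 8, 24 or 7 without Bcl6KO stage 1 library 1, 2 or 3. It was 44, 41 or 41 without WT stage 1 library 1, 2 or 3. Fitted with the Bcl6KO libraries alone, edgeR called 3 genes, 1 risen and 2 fallen, with 1224 of 13180 at an unadjusted p under 0.05. Bcl6, Myb and Itm2a did not pass there (edgeR adjusted p = 0.0593, 0.0593 and 0.0831). The 106 genes were called with a dispersion shared with WT libraries, although replicates agreed less in Bcl6KO stage 0 (r 0.678 to 0.738) than in WT stage 1 (0.871 to 0.903). The balance of rises and falls moved with the setting. It was 6 risen and 12 fallen with the Sp100 share as a covariate, 1 and 12 with voom quality weights, 2 and 9 with only Bcl6KO stage 0 library 1 kept, 19 and 20 with a replicate block and 10 and 17 with a genotype-specific one. Cd24a was called in all 25 alternatives, Bcl6 in 24, Rag1 and Myb in 22 and Itm2a in 21. As the gates were set on CD24, the fall of Cd24a follows from the sort and is no separate result. Other named calls were lost more often: Maf passed in 6, Cxcr6 in 7, Ly6a in 8, Cd8b1 and Il21r in 9, Dntt in 12, and B2m and Icos in 13. The other genes named so far as called between Bcl6KO stages, besides those with 0 counts in a group, passed in 16 to 18.

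**Figure D2:**
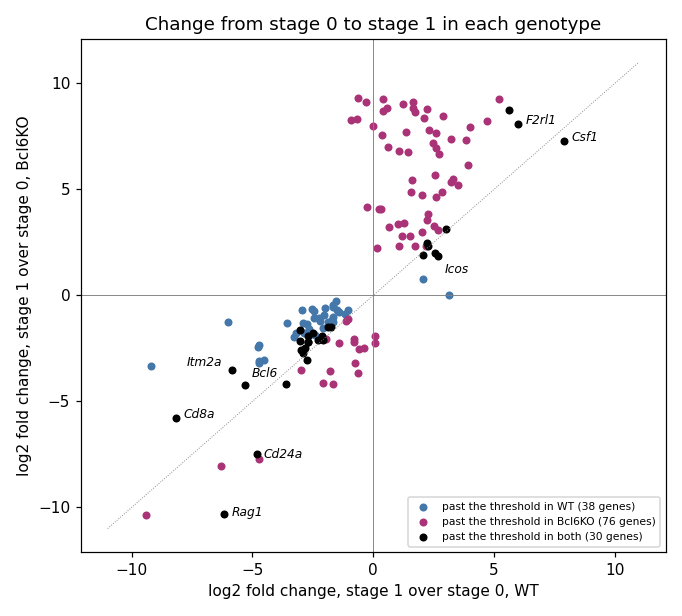
Log2 fold change from stage 0 to stage 1 in WT (horizontal) and in Bcl6KO (vertical) for the genes past the adjusted threshold in either genotype, 1 point per gene, with a dotted line of equal change. The 30 genes called in both (black) moved the same way, 9 up and 21 down, and points near 9 on the vertical axis include the 13 genes at 0 counts in Bcl6KO stage 0, whose fitted values are no bound.

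Of the genes called between stages, 30 were called in both genotypes, 9 risen and 21 fallen, against 0.046 and 0.145 expected for independent lists. The comparisons share no library, but their calls use a dispersion per gene estimated over all 12 libraries. The calls are thus not independent, and the expected numbers are no chance level for them. Among the 30 were Bcl6, the gate marker Cd24a, Cd8a, Rag1, Itm2a, Myb, Egr1, Egr2, Nr4a1 and Il21r, which fell, and Icos, Arl4c, B2m, Csf1, F2rl1 and Paqr8, which rose. Calls over the alternatives were not tallied for Nr4a1 between WT stages, nor for Egr2, Arl4c, Csf1, F2rl1 and Paqr8 between Bcl6KO stages. Signs were shared for 68 of the 68 genes called in WT and 99 of the 106 called in Bcl6KO. Over all 15704 genes the fold changes had r = 0.31, and over the 4858 more abundant genes r = 0.48; both are across genes, which are not independent replicates. The shared count was 49 without WT stage 0 library 2, 15 without WT stage 0 library 1 or Bcl6KO stage 0 library 3, and 11, 15 or 14 without WT stage 1 library 1, 2 or 3. It was 5, 11 or 5 without Bcl6KO stage 1 library 1, 2 or 3.

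**Figure D3:**
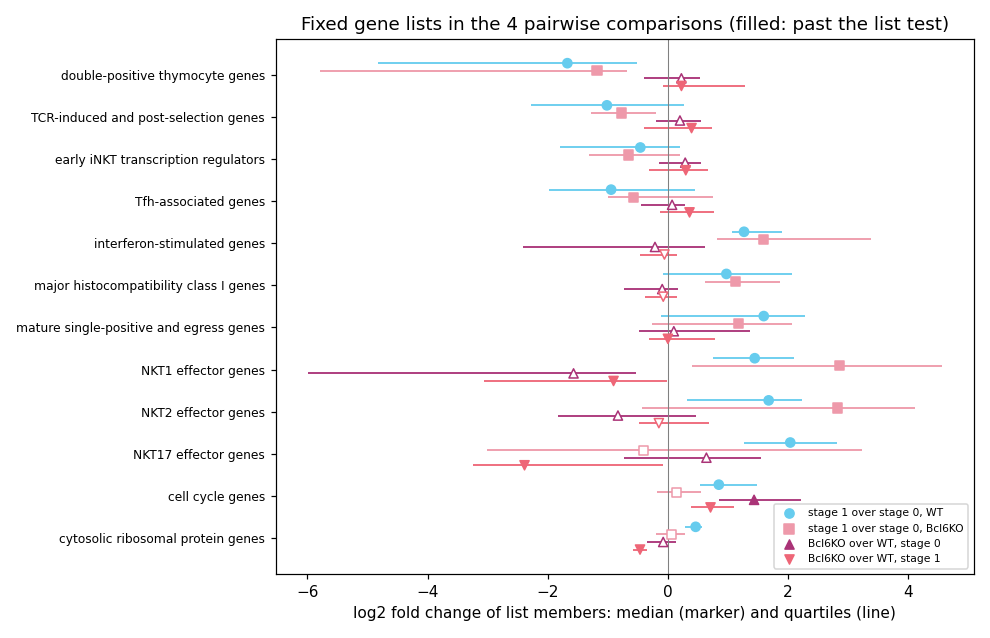
Median (marker) and quartiles (line) of the log2 fold changes of list members in the 4 pairwise comparisons, filled where the list passed camera at the preset correlation. Double-positive thymocyte genes had medians of -1.67 in WT and -1.18 in Bcl6KO between stages, and cell cycle genes medians of 1.43 and 0.71 between genotypes at stages 0 and 1.

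At stage 0, Bcl6KO cells held more of a cell cycle regulator and 2 signalling genes than WT cells. Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125162 to 127152193), the D-type cyclin 2 that drives entry into the cell cycle, stood at 720 ± 34.7 CPM in WT and 2241 ± 455 CPM in Bcl6KO (SD, n = 3 each). Camk1d (ENSMUSG00000039145, chromosome 2, 5293457 to 5714515), a calcium-dependent kinase, stood at 56.3 ± 14.9 and 416 ± 120 CPM. Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392), a binding protein of insulin-like growth factors, stood at 20.4 ± 2.35 and 258 ± 16.6 CPM. These 3 genes rose and 0 fell of 15704 tested, and 2309 had an unadjusted p under 0.05. They had log2 fold changes of 1.64 (SE 0.21), 2.89 (SE 0.39) and 3.66 (SE 0.52) and edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0340, 0.0340 and 0.0409. Each was higher in all 3 Bcl6KO libraries than in any WT library. Camk1d, Ccnd2 and Igfbp4 stayed past the threshold in 10, 11 and 9 of 24 alternatives.

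Cell cycle genes were higher in Bcl6KO as a list at stage 0, with a median of 1.43 and 39 of 40 members positive. None passed edgeR over all genes, 14 had risen adjusted over the list alone, and camera gave adjusted p = 9.74e-18, but adjusted p = 0.269 with an estimated correlation. Fry called 0 of the 31 lists between genotypes at stage 0. Mki67, the Ki-67 proliferation marker, stood at 375 ± 57.5 and 1845 ± 382 CPM (log2 fold change 2.30, SE 0.40, edgeR adjusted p = 0.1003). Top2a, the topoisomerase of dividing cells, chosen after its values were seen, stood at 91.3 ± 39.6 and 417 ± 73.5 CPM (2.19, SE 0.35, adjusted p = 0.0939). Genes known as BCL6-repressed in T and B cells had a median of 0.39 (15 of 26 positive, 1 risen, 3 adjusted over the list alone, camera adjusted p = 0.00973, adjusted p = 0.329 with an estimated correlation). The riser was Ccnd2, and the call ended without Bcl6KO stage 0 library 3 (camera adjusted p = 0.0511). The median was 0.23 without WT stage 0 library 3 and 0.03 without Bcl6KO stage 0 library 1. B cell markers had a median of 1.43 (8 of 11 positive, 0 adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.440 with an estimated correlation). That call ended without WT stage 0 library 2 or 3 or Bcl6KO stage 0 library 1 (camera adjusted p up to 0.335). Gamma-delta T cell markers had a median of -4.58, or -3.80 with zero-count genes at their bound (7 of 12 fallen adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.729 with an estimated correlation). That list rested on WT stage 0 library 2, which held Tcrg-C2, a gamma chain constant gene, at 548.91 CPM against 31.01 and 10.04 CPM in the other WT stage 0 libraries. The call ended without it (median -0.56, camera adjusted p = 0.692), while without Bcl6KO stage 0 library 1 or 2 it ended with medians of -4.47 and -4.82 (camera adjusted p = 0.272 and 0.125), near the one reported. Chosen after their values were seen, Il7r (2.97, SE 0.56), Zbtb7b, the CD4 lineage factor (3.95, SE 0.70), and Lig1, a DNA ligase (2.25, SE 0.44), each had edgeR adjusted p = 0.1003. So did the lower St8sia6, a sialyltransferase gene (-3.73, SE 0.65), and Ece1, an endothelin-processing enzyme (-2.75, SE 0.51).

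Sp100 and the low number of genes detected moved with these Bcl6KO stage 0 libraries. The count was 133, 61 risen and 72 fallen, without Bcl6KO stage 0 library 1, the library with the lowest Sp100 share of the 3 (10.8%, against 23.9% and 17.9%). It was 0 without any other stage 0 library, WT stage 1 library 1 or Bcl6KO stage 1 library 1, and 1 without Bcl6KO stage 1 library 3. Fitted with the stage 0 libraries alone, edgeR called 0 genes. It then had 773 of 12963 at an unadjusted p under 0.05, against 2309 of 15704 with the dispersion of all 12 libraries. With the Sp100 share as a covariate edgeR called 0 genes, with 1741 at an unadjusted p under 0.05, and DESeq2 without it called 1107, 356 risen and 751 fallen. The folds changed little with the covariate and their errors widened: 1.53 (SE 0.22) for Ccnd2, 2.85 (SE 0.45) for Camk1d and 3.28 (SE 0.57) for Igfbp4, with edgeR adjusted p = 0.173, 0.212 and 0.212. Over all alternatives they ran from 1.27 to 1.78, from 2.68 to 3.17 and from 3.28 to 3.75.

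**Figure D4:**
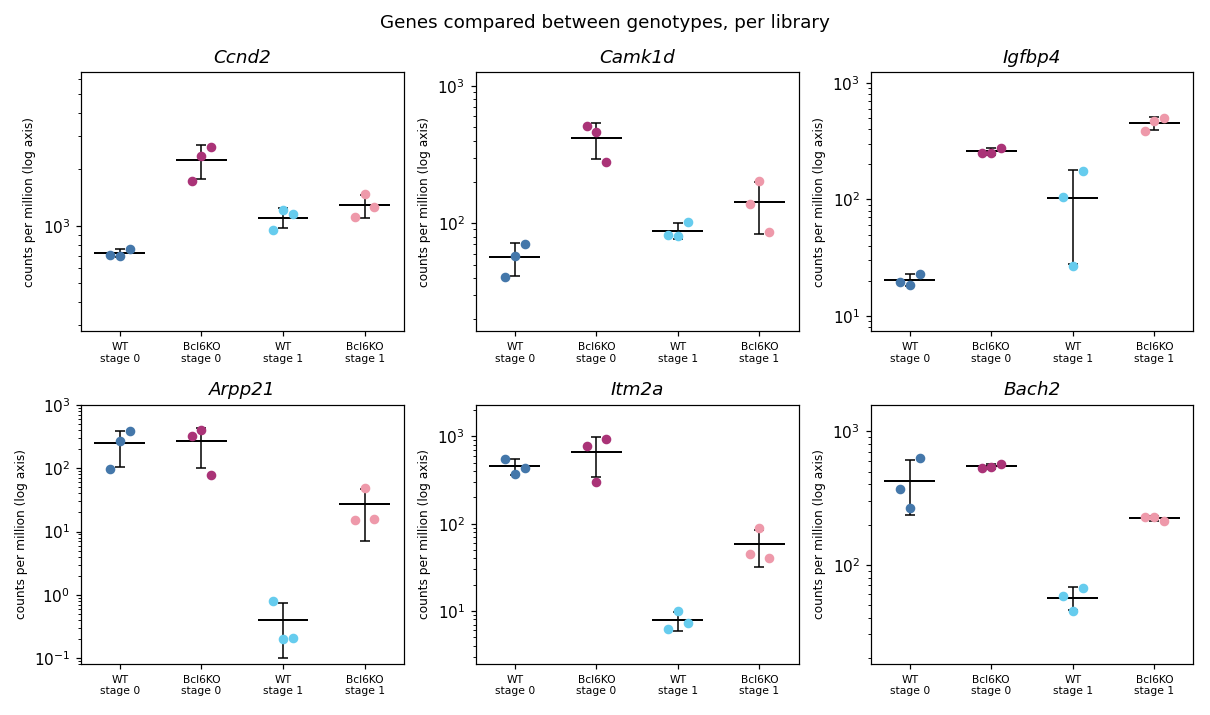
CPM (log axis) per library for 3 genes that rose in Bcl6KO at stage 0 (Ccnd2, Camk1d, Igfbp4) and 3 with the lowest p at stage 1, none of which passed (Arpp21, Itm2a, Bach2), with the mean as a long line and the SD as a bar. Igfbp4 averaged 20.4 CPM in WT and 258 CPM in Bcl6KO at stage 0, and Itm2a 7.88 and 58.0 CPM at stage 1.

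At stage 1, no gene passed the threshold between Bcl6KO and WT. Arpp21 stood at 0.400 ± 0.344 CPM in WT and 26.9 ± 19.8 CPM in Bcl6KO (SD, n = 3 each). Its WT level lay under the floor of 0.602 CPM, so the size of its fold is uncertain. Itm2a stood at 7.88 ± 1.99 and 58.0 ± 26.3 CPM and Bach2 at 56.8 ± 11.2 and 223 ± 9.35 CPM. These 3, chosen after their values were seen, had log2 fold changes of 5.98 (SE 0.92), 2.88 (SE 0.45) and 1.97 (SE 0.31). Each had edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.115, and all were higher in all 3 Bcl6KO libraries. EdgeR called 0 genes at stage 1, with 404 at an unadjusted p under 0.05 against 785 expected, while DESeq2 called 16, voom with quality weights 5 and edgeR without a filter 11. The 404 rest on a dispersion shared by all groups, although replicates agreed less in Bcl6KO stage 0 (r 0.678 to 0.738) than in WT stage 1 (0.871 to 0.903). Fitted with the stage 1 libraries alone, edgeR called 0 genes, with 966 of 13965 at an unadjusted p under 0.05. The low number thus does not show that the genotypes were alike at stage 1. Chosen in the same way, Tnfsf8 (4.57, SE 0.79), the adhesion gene Cd2 (2.38, SE 0.42) and Tns4, a tensin (4.04, SE 0.77), were higher. So were the survival gene Bcl2 (2.23, SE 0.47), Igfbp4 (2.14, SE 0.49) and the Wnt-pathway factor Lef1 (1.45, SE 0.36), while Ikzf3, which encodes Aiolos (-1.65, SE 0.34), was lower. Their edgeR adjusted p ran from 0.214 to 1.

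Among lists at stage 1, cytosolic ribosomal protein genes were lower in Bcl6KO (median -0.46, 55 of 58 negative, 0 fallen over all genes or adjusted over the list alone, camera adjusted p = 1.05e-11, adjusted p = 0.304 with an estimated correlation). Ribosomal protein genes took 2.08% and 1.87% of counts in Bcl6KO stage 1 libraries 2 and 3, where Sp100 took 2.62% and 3.77%. In library 1, with 0.0283% Sp100, they took 2.91%, within the WT stage 1 range of 2.59% to 3.55%. The list passed camera in 22 of 22 alternatives, the Sp100 covariate among them. All of these kept the preset correlation, so they do not test that setting. Fry called 0 of the 31 lists between genotypes at stage 1. Cell cycle genes were again higher (median 0.71, 35 of 40 positive, 0 adjusted over the list alone, camera adjusted p = 1.01e-10, adjusted p = 0.214 with an estimated correlation). TCR-induced and post-selection (median 0.39), Tfh-associated (0.36), early regulator (0.30) and double-positive thymocyte genes (0.22, or 0.21 at the bound) were higher. Camera gave adjusted p = 5.75e-04, 0.00135, 0.00410 and 0.0195, and adjusted p = 0.173, 0.173, 0.304 and 0.304 with an estimated correlation. Adjusted over the list alone, 1, 2, 2 and 1 of their members had risen. NKT17 (median -2.39, 7 of 10 negative), NKT1 (-0.91, 15 of 20 negative) and gamma-delta genes (-2.07, 11 of 12 negative) were lower. Camera gave adjusted p = 0.00107, 0.00107 and 2.93e-06, and adjusted p = 0.173, 0.304 and 0.304 with an estimated correlation. Mature single-positive genes passed camera narrowly (adjusted p = 0.0473, adjusted p = 0.476 with an estimated correlation), with a median of -0.00 and a mean of 0.19. Without WT stage 1 library 2 the double-positive and Tfh-associated calls ended (camera adjusted p = 0.355 and 0.0563). Without WT stage 1 library 1 or Bcl6KO stage 1 library 2 the early regulator call did (camera adjusted p up to 0.152). The mature single-positive call ended without any of 8 single libraries, among them WT stage 1 library 2 and Bcl6KO stage 1 library 2 (camera adjusted p up to 0.285).

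Medians at stage 1 also moved by over 1.5 times without single libraries. That of cell cycle genes was 0.46 without WT stage 1 library 2, and that of NKT1 genes -1.60 without Bcl6KO stage 1 library 1. TCR-induced genes had 0.23 without Bcl6KO stage 1 library 2 or 3, Tfh-associated genes 0.18 without library 3 and early regulators 0.13 without library 2. Double-positive thymocyte genes had 0.46 or 0.48 without WT stage 1 library 1 or 3, and 0.03, 0.12 or 0.39 without Bcl6KO stage 1 library 1, 2 or 3.

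Whether the genotype effect differed between stages was tested directly. Cell cycle genes had a difference of -0.73 (median, stage 1 minus stage 0, 35 of 40 negative) and cytosolic ribosomal protein genes one of -0.37 (48 of 58 negative). Each had camera adjusted p = 1.75e-04, and adjusted p = 0.872 and 0.928 with an estimated correlation. Fry called 0 of the 31 lists for this difference. In each list 0 members passed adjusted over the list alone. EdgeR called 0 single genes, with 1221 at an unadjusted p under 0.05 and a smallest adjusted p of 0.483, while DESeq2 called 199, voom 0 and edgeR without a filter 7. Ccnd2, which rose at stage 0, stood at 1114 ± 138 and 1289 ± 182 CPM at stage 1, and its difference of -1.43 (SE 0.29) had edgeR adjusted p = 0.483. The cell cycle call ended without Bcl6KO stage 0 library 3 (camera adjusted p = 0.158, median -0.62) and the ribosomal one without WT stage 0 library 3 (0.0588, median -0.22).

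Markers of cells outside the gate were tested in the same way. Besides the B cell and gamma-delta lists already given, those of macrophages and monocytes, dendritic cells, thymic epithelium, regulatory T cells and the CD8 lineage passed camera in no comparison. The smallest adjusted p was 0.0974 for CD8 lineage genes between stages in Bcl6KO. Medians between genotypes at stage 0 were 0.83, 0.07, -0.01, 0.07 and -0.62 in that order. The iNKT receptor segments had medians of -0.00 and 0.06 between genotypes at stages 0 and 1. The constant gene Trbc2 stood at 1269 ± 272 and 1299 ± 246 CPM at stage 0 in WT and Bcl6KO.

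**Figure D5:**
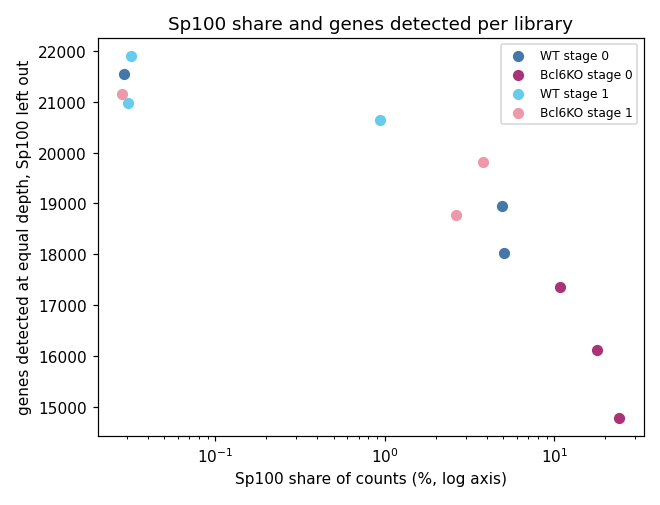
Sp100 share of each library's counts (percent, log axis) against the number of genes detected at equal depth with Sp100 left out, 1 point per library, coloured by group. The 3 Bcl6KO stage 0 libraries, at 10.8% to 23.9%, detected the fewest genes, between 14782 and 17361.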

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

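The tests with the Sp100 share as a covariate, with only Bcl6KO stage 0 library 1 kept and of other splits of the libraries were chosen only after the results were seen, and the test on GC content and transcript length was written before its result.

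A test of the difference between stages flagged cell cycle genes, whose median genotype effect was 0.73 lower at stage 1 than at stage 0 (difference -0.73), and cytosolic ribosomal protein genes (difference -0.37). Both passed camera at the preset correlation only (adjusted p = 1.75e-04 each), and no single gene passed edgeR. All 100 splits of the libraries gave at least the 0 genes found, as any split must, so these splits say nothing about chance (the highest of the others gave 3).

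Cell cycle genes were higher in Bcl6KO at stage 0 by a median of 1.43. With the Sp100 share as a covariate the median was 1.47 (camera adjusted p = 1.01e-14). The covariate's slope rests on the spread within groups, and this argues only against an effect that followed Sp100 there. At stage 0 the shares did not overlap between genotypes (0.0289% to 5.03% in WT, 10.8% to 23.9% in Bcl6KO). Library quality particular to the Bcl6KO stage 0 libraries thus stays open. After removal of a trend on GC content and transcript length the median was 1.60 over all 40 genes, which argues against GC content or transcript length as the whole cause. The list stayed past the camera threshold in 22 of 22 alternatives, with medians between 0.93 and 1.69, but all of these kept the preset correlation. With an estimated correlation the list did not pass, and fry called 0 lists between genotypes at stage 0. A larger share of dividing cells among the sorted stage 0 cells of Bcl6KO mice could give the same values and was not tested. With 1 of 10 splits of the 6 stage 0 libraries, the labelled one, giving as many as 3 genes and the highest other 0, too few splits exist for chance to be judged.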

How the results depend on the processing

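The tests with voom quality weights, the Sp100 share as a covariate, only Bcl6KO stage 0 library 1 kept, a genotype-specific replicate block and without Sp100, Malat1, rRNA-like and mitochondria-like genes were chosen only after the data were seen; the others were planned. Counts are given in the order genotype at stage 0 (3), genotype at stage 1 (0), stages in WT (68), stages in Bcl6KO (106), difference of genotype effects (0) and genes shared by both genotypes (30). Where a count moved, the cause was not tested unless the alternative's own construction shows it.

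RLE size factors (3, 0, 71, 105, 0, 30), a filter at 5 CPM (3, 0, 79, 141, 0, 33), nonrobust dispersion (3, 0, 62, 113, 0, 28) and removal of Sp100, Malat1, rRNA-like and mitochondria-like genes (3, 0, 67, 79, 0, 28) kept every count within 1.5 times. DESeq2 gave 1107, 16, 385, 1483, 199 and 186 and kept all 3, 68 and 106 genes. It made more false calls in counts simulated from edgeR's own dispersions, which is no fair ranking of the methods. No low-count filter gave 103, 11, 142, 309, 7 and 59. A fold threshold of 1.5 in glmTreat, stricter by construction, gave 0, 0, 31, 45, 0 and 11. Fitting only the groups compared, with fewer libraries and a dispersion estimated from these alone, gave 0, 0, 96, 3 and 2 shared. Voom weights gave 0, 5, 301, 13, 0 and 11, the Sp100 share as a covariate 0, 0, 42, 18, 0 and 14, and only Bcl6KO stage 0 library 1 kept, its group's lone library assumed to vary like the others, 1, 0, 146, 11, 0 and 8.

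The labels do not say whether replicate numbers pair libraries, and it stays open: 5 of 18 same-number pairs had r above 0.1, the 6 of one genotype had r from 0.0106 to 0.187, and Xist was low in both Bcl6KO libraries numbered 2 (2118 and 670 counts). The 18 include pairs across genotypes, which cannot share a pool. For 7 of 12 libraries the best partner had the same number. Between Bcl6KO stages same-number r was 0.0735, 0.0248 and 0.0352, against at most 0.00727 for other numbers. Between WT stages numbers 2 and 3 matched best with their own number, and number 1 did not. If pools were shared, the stage tests would be paired, which only the blocked fits allow for. A replicate block gave 1, 0, 53, 39, 0 and 16, and a genotype-specific replicate block 49 (WT stages), 27 (Bcl6KO stages) and 15 shared.

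Leaving out each library in turn gave 0 to 133, 0 to 1, 20 to 139, 7 to 277, 0 to 0 and 5 to 49. Lists past camera, 4, 10, 17, 12 and 2 in the first 5 comparisons, ranged over 2 to 6, 8 to 11, 17 to 18, 9 to 14 and 1 to 4. With the correlation estimated per list they numbered 0, 0, 5, 4 and 0, and with fry in place of camera 0, 0, 15, 8 and 0. The Sp100 share as a covariate left 2 lists at stage 0, and only Bcl6KO stage 0 library 1 kept left 1 for the difference of genotype effects.

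Of named-gene results, 642 of 775 for WT stages, 424 of 750 for Bcl6KO stages, 316 of 383 for genotype at stage 0 and 359 of 383 at stage 1 kept direction and side of the threshold. Reversed were Cd24a between genotypes at stage 0 (-0.00132 with the Sp100 share as a covariate, 0.54 as reported) and Cd44 at stage 1 (-0.35 without WT stage 1 library 2, -0.11 and -0.10 without Bcl6KO stage 1 library 1 and 3, 0.13 as reported, and up to 0.85 without WT stage 1 library 1). None of these passed a test, and the cause was not tested. The spread between libraries (biological coefficient of variation 0.835) limited detection, so that 4-fold changes were mostly missed in simulated counts.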

Other observations

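The tests on Xist, Ddx3y and Eif2s3y, on the source of the Sp100 counts, on the genes of stage 0 that were higher in Bcl6KO at stage 1 and of other splits of the libraries were chosen only after the results were seen.

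Xist, the noncoding RNA of the inactive X chromosome, was counted 2118 times in Bcl6KO stage 0 library 2 and 670 times in Bcl6KO stage 1 library 2, against 23383 to 43920 times in the other 10 libraries. The sex of the mice in each pool is not given in the sources used here. At stage 1 the Y-linked Ddx3y had 227 to 264 counts in Bcl6KO and 66 to 111 in WT libraries. Eif2s3y, also Y-linked, had 222 to 310 and 59 to 87. At stage 0 the ranges overlapped (Ddx3y 27 to 929 and 57 to 138). Sex-linked genes as a list had genotype medians of 1.02 at stage 0 and 1.31 at stage 1, without passing camera. The sexes may thus be unevenly mixed between genotypes, and an effect on the genotype comparisons was not tested.

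Sp100 took 17.5 ± 6.57% of counts in Bcl6KO stage 0 and 3.32 ± 2.86% in WT stage 0. Within groups its share fell as genes detected at equal depth rose (r = -0.80, exact permutation p = 0.00694 over 1296 orders), which fits low library complexity. The values argue against genomic DNA carry-over, since the share of receptor family genes changed 1.09 times and that of Sp100 5.28 times. For interferon induction of Sp100, the third quartile of interferon-stimulated genes was 0.62 against 2.85 (SE 1.96) for Sp100, which argues against it only weakly, given that error. A 5S rRNA gene copy with 0 counts lies inside an Sp100 exon, and reads from 5S rRNA could have been counted as Sp100, which counts per gene cannot test.

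Among the genes with the lowest p that were higher in Bcl6KO at stage 1, 9 had fallen with stage in WT (Bcl6, Cd2, Lef1, Tnfsf8, Itm2a, Arpp21, Bach2, Hectd2 and Bcl2). Of all 57 genes that fell with stage in WT, 47 were higher in Bcl6KO at stage 1 (median 0.64), and of all 40 that fell with stage in Bcl6KO, 18 were (median -0.01). The first set was chosen for low values in the same WT stage 1 libraries, which favours a higher level in Bcl6KO, and the second in the same Bcl6KO stage 1 libraries, which favours a lower one, so neither tally decides. Carry-over of stage 0 cells would need a median share of 24.6% for the 9 genes (lowest 4.09%), while Cd24a, Rag1 and Dntt allow at most 0.952%. Picking genes that were high in this same comparison raises the share they need to an unknown extent, and Cd24a was a gate marker. These shares thus do not decide on carry-over. With the Sp100 share as a covariate the median log2 fold change of the 9 genes was 1.99 (2.30 without it, lowest gene 1.09). As the genes were picked for their p in this comparison, that does not decide on library quality tracked by Sp100, which stays open. Later loss of these transcripts in Bcl6KO cells, or a shift among cells that had already lost Cd24a, could give the same values, and neither was tested.

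No gene passed edgeR between genotypes at stage 1, and 10 of 10 splits of the stage 1 libraries gave at least the 0 genes found, as any split must (the highest of the others gave 0), so these splits say nothing about chance. For the stages, 1 of 10 splits in WT gave as many as 68 genes and 1 of 10 in Bcl6KO as many as 106, in both cases the labelled split, and the highest of the others gave 0. With 10 splits each, too few exist for chance to be judged from these counts alone.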
